A study of Sus scrofa with 23 samples.

How the data were processed

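Total RNA of Longissimus muscle from 23 pigs was extracted with Trizol, labelled with Cy3 and hybridised to Agilent single-colour arrays, 1 array for each pig, per the labels' protocols. The labels gave 7 low-RFI pigs and 8 high-RFI pigs fed freely, and 8 high-RFI pigs fed at the level of the low line, all at 115 kg. Each array stood for a separate pig, and the highest correlation between arrays was 0.99. The spot intensity values were background-subtracted and detrended within each array by Feature Extraction 10.7.3.1 and not scaled between arrays, per the file headers. The mean pixel intensity of each spot and the median intensity of its local background, per the file headers, were used for 1 background correction only. The submitters' processing notes name R 2.10.0. The deposited log2 value table held 26410 probes, and each of its columns had a median of 0. Its values were the log2 processed signal minus a constant for each array, as a comparison with the scanner files showed, so its scale and its centring were known. The rule by which its probes were chosen was not stated. Of its probes 17668 were well above background on all 23 arrays, and the dimmest were so on 14. The table was used as an alternative only.

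For the main setting, the processed signal of 43803 non-control spots was taken to log2, the array's 75th percentile over these spots was subtracted, spots that the scanner software marked as non-uniform or as population outliers were set to missing, and spots of the same probe were averaged. The 1417 control spots were left out. Of 43603 probes, 27785 were kept, those well above background on at least 6 arrays of 1 group, with 470 values missing in 459 probes. Symbols were matched to 12248 probes, 7210 by accession, 3386 by the symbol in the files, 63 by an older symbol, 177 by a symbol in no list and 1413 by gene ID, which gave 5389 symbols. Another 31348 probes matched no name and 6 matched several. Each of the 4327 measured genes was represented by its kept probe with the highest mean. Gene order came from the Sscrofa11.1 annotation. A probe whose symbol was at odds with its description in the files was not named.

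The 3 groups were fitted together in limma 3.58.1 under R 4.3.3, with 3 contrasts and an F test over the groups. Moderated p were adjusted by Benjamini-Hochberg over the 27785 probes, with a threshold of adjusted p 0.05, and standard errors are those of the moderated fit. Of 33 gene lists written before the files were opened, 32 had at least 5 measured genes and were tested with camera at a preset correlation between genes of 0.01, on 4283 genes without a missing value, with 44 left out. Camera with an estimated correlation and fry were run beside it. P-values were adjusted over the 32 lists within a comparison. The exact permutation of list means, run over all divisions of the pigs of a comparison, was added after the data were seen. Intervals are 95% intervals with slide as a fixed block.

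Genes were named by a rule written before the files were opened. For each comparison it took up to 8 genes past the threshold with the largest change in each direction, up to 4 genes with the smallest p in the direction of each called list, and the 5 genes with the smallest p where fewer than 5 passed. Some genes that the rule took are not reported here, and no others were put in their place. Other probes that are named were chosen after their values were seen.

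Slide and scan day came from the file headers. Other settings fixed in advance were median centring, quantile normalization, normexp background correction with an offset of 50, the deposited values, filters on dim probes, trend and robust variance, array weights, slide as a fixed or random block, the replicate number as a block, a threshold of 0.01, an added minimum absolute log2 difference of 0.5, leaving out each pig in turn, fits of 2 groups only and the mean of a gene's probes. Camera has no robust setting, so for the lists that alternative used the trend alone. The planned normexp fit gave background SDs over 100 on 5 arrays. For this reason 3 further normexp estimates were tried after the data were seen: a fit on the 153 negative control spots, its robust form, and the planned fit without those 5 arrays. A block for scan day, a fit without the 4 arrays of slide 3, the ribosomal list without 1 pig by exact permutation, and all lists without each pig in turn were also added then.

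Simulated data with known changes were run through the same scripts first, on 27326 probes without missing values. Of 100 probes changed by 1 log2 unit, 80 were recovered for low-RFI against high-RFI, 80 for restricted against high-RFI and 76 for low-RFI against restricted pigs. Of 100 changed by 0.5, 29, 36 and 36 were recovered, and 3, 8 and 6 of 27126 unchanged probes were called. A simulated shift of 0.2 in the ribosomal list was called and 0 other lists were. The simulated probes and genes varied independently of each other and had no slide effect. These runs therefore do not show how often correlated genes lead to false calls of lists in the real data. The correlation of differences between comparisons was compared with 100 draws of unchanged groups and with 35 halvings of the shared group. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.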

Results

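Gene expression was measured in Longissimus muscle, the long muscle of the back, from 23 pigs at 115 kg body weight. Residual feed intake (RFI) is the part of an animal's feed intake that growth and maintenance do not account for, and the pigs came from lines with low or high RFI. There were 7 low-RFI pigs and 8 high-RFI pigs with free access to feed. Another 8 were high-RFI pigs whose feed was limited to what the low line ate. RNA of each pig was hybridised to 1 single-colour array. On each array between 41.7% and 79.0% of the probes lay well above background, with medians of 69.3% in the low-RFI, 67.95% in the high-RFI and 67.2% in the restricted group, and the number of arrays limits the precision. The arrays were spread over 6 slides and 2 scan days, with all 3 groups on every slide. Slide 3 had the lowest median share, 50.1%, with 41.7% to 58.8% on its 4 arrays. The median correlation of an array with the others of its group ran from 0.976 to 0.988. The first principal component held 16.6% of the variance, of which slide accounted for 60.7% and group for 1.6%, whereas group accounted for 35.0% of the second, which held 11.1%. Levels are log2 signal minus the array's 75th percentile, group values are means ± SD, and differences are log2 values with limma's standard error. Of 27785 probes tested, 38 differed among the 3 groups at an adjusted p under 0.05 in limma's moderated F test, and 3468 had an unadjusted p under 0.05 where 1389 would be expected with no difference. The number past the threshold was 24 without low-RFI replicate 1 and 70 without restricted replicate 1. Probes are not independent of each other. How far counts at an unadjusted p under 0.05 range with no difference was not measured, here or in the comparisons below.

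The first comparison asked how the lines differed with free access to feed. CD40, a receptor of B cells and other antigen-presenting cells, fell in low-RFI pigs, from 1.79 ± 0.23 (n = 8) to 0.48 ± 0.40 (n = 7), a difference of -1.31 (SE 0.17, limma adjusted p 0.000684). All 3 probes of CD40 passed the threshold, at -1.29, -1.31 and -1.37. SAL1, a salivary lipocalin that binds small odorants, fell from -1.86 ± 0.74 to -3.63 ± 0.70, a difference of -1.76 (SE 0.33, limma adjusted p 0.0239), and was well above background in 5 of the 7 low-RFI pigs. OAZ3, an antizyme that inhibits the first enzyme of polyamine synthesis, fell from -2.28 ± 0.16 to -2.93 ± 0.15, a difference of -0.65 (SE 0.13, limma adjusted p 0.0424). An OAZ3 probe of lower mean over all arrays was not well above background in any low-RFI pig but was in all 8 high-RFI pigs. Its signal was at least 8.28-fold lower in the low line (limma adjusted p 0.000235), far more than the brightest probe's, for an untested reason. Such bounds compare the bright group's mean with the dim group's mean of, per array, the lowest signal among probes well above background or the probe's own signal where that was higher.

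In all, 34 of 27785 probes passed the threshold between the lines at free feeding, 12 higher and 22 lower in low-RFI pigs, and 3087 had an unadjusted p under 0.05 where 1389 would be expected. Of the 34 probes, 8 carried a gene symbol, and 3 of 4327 named genes passed on their brightest probe. A probe of DLD, the dihydrolipoamide dehydrogenase shared by mitochondrial dehydrogenase complexes, also passed at -0.71 (SE 0.12, limma adjusted p 0.0063). It was chosen after its values were seen, and the brightest DLD probe, at -0.34, did not pass (adjusted p 0.143). The next 2 genes by p were MTHFD1, an enzyme of folate metabolism, at -1.11 (SE 0.24, limma adjusted p 0.0717), and the stress-activated kinase MAPK12 at 0.57 (SE 0.13, limma adjusted p 0.074). In a fit with slide as a block CD40 stood at -1.37 (limma adjusted p 0.00026), while SAL1 at -1.64 (0.0844) and OAZ3 at -0.63 (0.0851) missed the threshold, and 18 of the 34 probes were still past it. CD40, SAL1 and OAZ3 were lower in low-RFI pigs on 6 of 6 slides, and on scan days 1 and 2 they differed by -1.28 and -1.39, -2.41 and -1.03, and -0.70 and -0.60. Leaving out high-RFI replicate 2 or low-RFI replicate 5 left 22 probes each. SAL1 missed the threshold without low-RFI replicate 5 (limma adjusted p 0.0615) or 7 (0.0685), and OAZ3 missed it in 14 of the 23 fits that left out 1 pig. SAL1 also missed it with no filter on dim probes (0.056) and without the 4 arrays of slide 3 (0.113), and OAZ3 with no filter (0.0997) and with median centring (0.0506). The replicate number as a block ended both calls (0.0804 and 0.0761). Robust normexp on the negative controls, added after the data were seen, brought SAL1 to -0.92 (0.0838) and OAZ3 to -0.31 (0.254). The planned normexp correction ended all 3 calls, with CD40 at -1.18 (0.555), SAL1 at -0.63 (0.988) and OAZ3 at -0.07 (0.988). Its fit was poor on 5 arrays, which limits its values here and wherever they are given below.

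**Figure D1:**
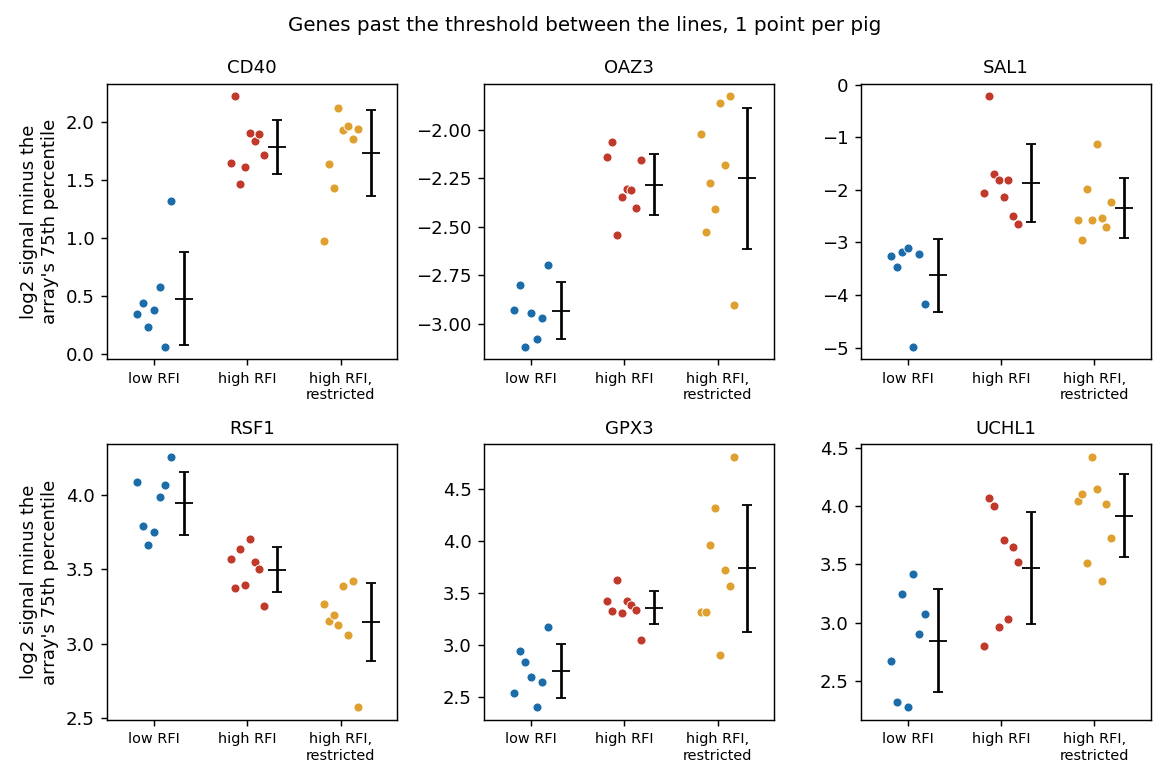
Level of 6 genes past the threshold between the lines, in log2 signal minus the array's 75th percentile (vertical axis), by group (horizontal axis). Each point is 1 pig and each bar the mean ± SD of its group, with CD40 at 0.48 ± 0.40 in low-RFI, 1.79 ± 0.23 in high-RFI and 1.73 ± 0.37 in restricted high-RFI pigs.

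Genes of cytosolic ribosomal proteins and of translation factors and mTOR signalling were higher as groups in low-RFI pigs. All 39 measured genes of cytosolic ribosomal proteins had a positive difference, with a mean of 0.21 (camera adjusted p 8.32e-21), but the call was lost with an estimated correlation (p 0.031, adjusted p = 0.524). The planned normexp background correction turned the mean to -0.02. An exact two-sided permutation of the mean per pig, added after the data were seen, gave p 0.0014 (adjusted 0.0448). None passed over all probes and 29 passed when adjusted over the list alone. Genes with a small p included RPL14 at 0.51 (SE 0.13), RPLP0 at 0.28 (SE 0.08) and RPS12 at 0.24 (SE 0.07), with limma adjusted p between 0.146 and 0.183. The group means were 7.90 ± 0.08 in low-RFI and 7.68 ± 0.12 in high-RFI pigs, and the shift was 0.20 (95% interval 0.08 to 0.32) with slide as a block, 0.26 and 0.15 on scan days 1 and 2, and positive on 6 of 6 slides. Genes of translation factors and mTOR signalling, the pathway that couples nutrients to protein synthesis, were higher in 14 of 17 cases (mean 0.17, camera adjusted p 0.00403; adjusted p = 0.524 with an estimated correlation). Among these, EEF1A1 stood at 0.50 (SE 0.18), EEF2K at 0.52 (SE 0.19), EIF2S2 at 0.27 (SE 0.09) and EIF2B5 at 0.22 (SE 0.08), and none passed, also when adjusted over the list alone. As written, the list joins genes that promote protein synthesis with genes that restrain it, such as EEF2K. Its mean therefore gives no direction of protein synthesis. The list's shift with slide as a block was 0.17 (0.04 to 0.29), with 0.22 and 0.10 on scan days 1 and 2 and a positive sign on 4 of 6 slides. The planned normexp correction ended its call, at 0.025 (camera adjusted p 0.594).

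Glycolytic and fast fibre genes were also higher as groups in low-RFI pigs, although both list means turned negative under the planned normexp correction, to -0.06 and -0.14. Of 15 genes of glycolysis, 13 were higher (mean 0.16, camera adjusted p 0.00286; adjusted p = 0.532 with an estimated correlation), among them the enolase ENO3 at 0.30 (SE 0.10), PGAM2 at 0.29 (SE 0.11) and GPI at 0.26 (SE 0.10). PGAM1 stood at 0.46 (SE 0.17) on its brightest probe and at -0.36 on the other. Of 16 fast fibre genes, 14 were higher (mean 0.13, camera adjusted p 0.00533; adjusted p = 0.524 with an estimated correlation), with the contractile genes TNNI2 at 0.21 (SE 0.10), TPM1 at 0.18 (SE 0.08) and TNNC2 at 0.16 (SE 0.08). MYH1 stood at 0.27 (SE 0.12), a value left uncertain by near-identical myosin copies. Genes of the proteasome, which degrades ubiquitin-tagged proteins, were higher in 15 of 18 cases (mean 0.11, camera adjusted p 0.017; adjusted p = 0.605 with an estimated correlation; -0.09 under the planned normexp correction). PSME1 stood at 0.31 (SE 0.10), PSMB6 at 0.24 (SE 0.09), PSMC5 at 0.19 (SE 0.10) and PSMB5 at 0.19 (SE 0.10). No gene of these 3 lists passed, over all probes or adjusted over the list alone. The shifts with slide as a block were 0.15 (-0.02 to 0.32), 0.13 (0.005 to 0.25) and 0.10 (-0.01 to 0.21). On scan days 1 and 2 they were 0.23 and 0.09, 0.16 and 0.11, and 0.15 and 0.06, with positive signs on 5, 4 and 5 of 6 slides. The proteasome call was lost without low-RFI replicate 5 (camera adjusted p 0.111) or high-RFI replicate 1 (0.0865). It was also lost without the 4 arrays of slide 3 (0.053) and with robust normexp on the negative controls (0.0803), which ended the fast fibre call too (0.08, 0.0834). Quantile normalization ended the calls of glycolysis (0.07, camera adjusted p 0.078) and of fast fibre genes (0.022, 0.685).

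Genes of respiratory complexes I to IV and of the tricarboxylic acid cycle were lower as groups in low-RFI pigs, while ATP synthase (mean -0.07, camera adjusted p 0.0896) and fatty acid uptake and oxidation (0.01, 0.607) were not called. Respiratory complexes II to IV were lower in 10 of 12 cases (mean -0.16, camera adjusted p 5e-04; adjusted p = 0.524 with an estimated correlation), with the electron carrier CYCS at -0.36 (SE 0.12), SDHD at -0.27 (SE 0.12), COX7A2 at -0.26 (SE 0.13) and COX7A1 at -0.17 (SE 0.09). Complex I was lower in 8 of 10 cases (mean -0.12, camera adjusted p 0.00742; adjusted p = 0.524 with an estimated correlation), with NDUFB9 at -0.33 (SE 0.14), NDUFS6 at -0.24 (SE 0.09) and NDUFA4 at -0.16 (SE 0.10). The tricarboxylic acid cycle with pyruvate dehydrogenase was lower in 12 of 13 cases (mean -0.15, camera adjusted p 0.00214; adjusted p = 0.524 with an estimated correlation), with DLD as above, MDH1 at -0.41 (SE 0.18), PDHA1 at -0.29 (SE 0.16) and DLAT at -0.19 (SE 0.11). Adjusted over the list alone, 1 gene of this list fell and none of either respiratory list did. Slide-blocked shifts were -0.14 (-0.31 to 0.04), -0.10 (-0.26 to 0.05) and -0.12 (-0.29 to 0.06). On scan days 1 and 2 they were -0.19 and -0.13, -0.14 and -0.11, and -0.15 on both days, with negative signs on 5, 5 and 4 of 6 slides. The tricarboxylic acid cycle mean was -0.10 without high-RFI replicate 3.

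Lists of immune, chaperone, matrix and fat cell genes were called lower in low-RFI pigs, and chance is not excluded for the number of lists called. The major histocompatibility complex, which presents antigen, was lower in 15 of 17 cases (mean -0.23, camera adjusted p 0.00016; adjusted p = 0.524 with an estimated correlation), and 4 genes fell when adjusted over the list alone. SLA-2 stood at -0.65 (SE 0.23), SLA-5 at -0.62 (SE 0.19), SLA-3 at -0.62 (SE 0.22) and SLA-8 at -0.39 (SE 0.13), all uncertain because these genes are near-identical copies. Leukocyte and macrophage markers were lower in 13 of 15 cases (mean -0.23, camera adjusted p 0.0262; adjusted p = 0.605 with an estimated correlation), with S100A8 at -1.19 (SE 0.52), S100A12 at -0.68 (SE 0.38), C1QA at -0.37 (SE 0.25) and CD14 at -0.21 (SE 0.11). S100A8 was well above background on 4 of 7 low-RFI and 6 of 8 high-RFI arrays. The leukocyte call was lost without low-RFI replicate 5 (camera adjusted p 0.0859), 6 (0.0831) or 7 (0.107) or high-RFI replicate 3 (0.0892) or 7 (0.0675). It was also lost with quantile normalization (0.0623), the planned normexp correction (-0.08, 0.0608), no filter on dim probes (-0.13, 0.0646) and the replicate number as a block (0.0801). Robust normexp on the negative controls (-0.13, 0.0581) and leaving out slide 3 (0.053) ended it as well. Heat shock and chaperone genes were lower in 12 of 14 cases (mean -0.26, camera adjusted p 0.000368; adjusted p = 0.524 with an estimated correlation), with HSPH1 at -1.10 (SE 0.44), HSP90AA1 at -0.41 (SE 0.13), HSP90B1 at -0.30 (SE 0.13) and HSPD1 at -0.27 (SE 0.10). Fibroblast and extracellular matrix markers were lower in 14 of 21 cases (mean -0.14, camera adjusted p 0.00814; adjusted p = 0.524 with an estimated correlation), and 2 fell when adjusted over the list alone. Fibronectin, FN1, stood at -0.69 (SE 0.17), fibrillin, FBN1, at -0.60 (SE 0.16), TIMP3 at -0.33 (SE 0.15) and COL4A1 at -0.32 (SE 0.17), and without high-RFI replicate 2 the list mean was -0.09. The replicate number as a block ended the matrix call (-0.10, camera adjusted p 0.0636).

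Adipocyte markers were lower in 10 of 11 cases (mean -0.45, camera adjusted p 0.00883; adjusted p = 0.524 with an estimated correlation), with the lipase LIPE at -0.72 (SE 0.26), CEBPA at -0.87 (SE 0.42), FABP4 at -0.53 (SE 0.32) and AQP7 at -0.44 (SE 0.26). Without high-RFI replicate 2 the adipocyte mean was -0.27 (camera adjusted p 0.0539) and without replicate 1 it was -0.33 (0.0865), both short of the threshold. No adipocyte, leukocyte or heat shock gene passed, also when adjusted over the list alone. Slide-blocked shifts of the histocompatibility, leukocyte, heat shock, matrix and adipocyte lists were -0.27 (-0.52 to -0.03), -0.20 (-0.61 to 0.20), -0.24 (-0.55 to 0.06), -0.14 (-0.36 to 0.07) and -0.39 (-1.07 to 0.28). On scan day 1 they were -0.26, -0.29, -0.32, -0.27 and -0.51, and on scan day 2 they were -0.21, -0.14, -0.17, 0.01 and -0.39. The mean shift of the matrix list was thus negative on day 1 but not on day 2, and whether the days differed was not tested. The histocompatibility list was lower on 6 of 6 slides and each of the other 4 lists on 4. Of 32 lists tested, 13 were called, and the other 19 had camera adjusted p of 0.0896 or more, beginning with ATP synthase. With an estimated correlation 0 of the 32 lists were called, although 1 was with fry and 4 had an unadjusted exact permutation p under 0.05. Random regroupings of the same pigs called up to 18 lists, and 10 of 100 splits called at least 13, so the number of lists alone is within what chance gives. These regroupings were not kept within slide, whereas the real groups were spread over all slides.

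**Figure D2:**
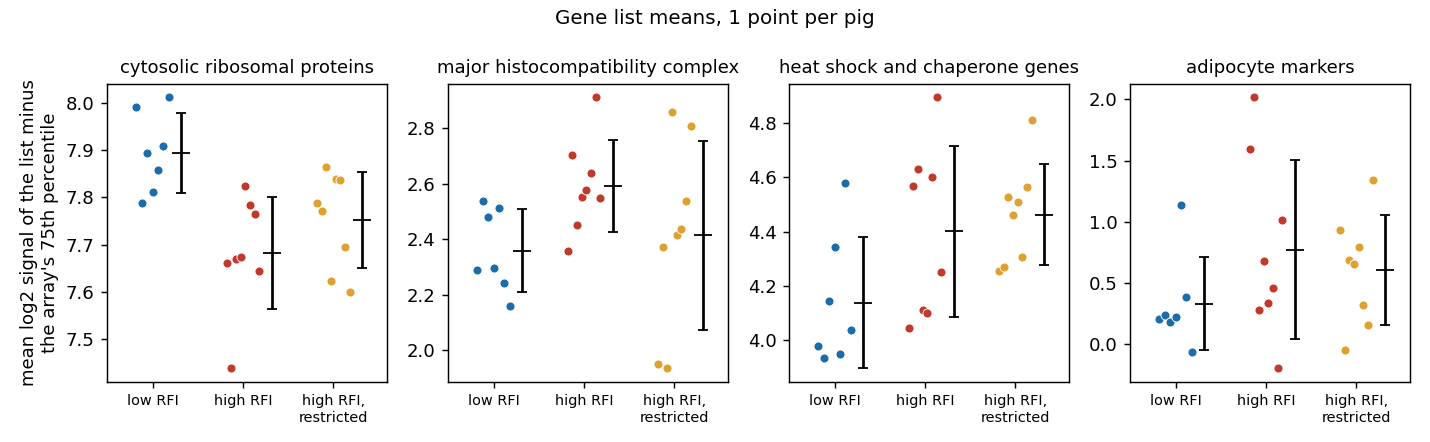
Mean of 4 gene lists in each pig, in log2 signal minus the array's 75th percentile (vertical axis), by group (horizontal axis). Each point is 1 pig and each bar the mean ± SD of its group. The ribosomal list mean is 7.90 ± 0.08 in low-RFI, 7.68 ± 0.12 in high-RFI and 7.75 ± 0.10 in restricted high-RFI pigs, and 1 high-RFI pig lies apart at 7.44.

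The second comparison asked what restricting the feed of the high line changed. No named gene passed on its brightest probe, and 1 of 27785 probes did, a probe of PAN3, a subunit of an enzyme that shortens poly(A) tails. It fell from -1.44 ± 0.24 to -2.24 ± 0.34 (n = 8 each), a difference of -0.81 (SE 0.13, limma adjusted p 0.0475). The probe was chosen after its values were seen, the brightest PAN3 probe stood at -0.04 (adjusted p 0.951), and with slide as a block the difference was -0.75 (limma adjusted p 0.102). Genes with a small p were lower and did not pass, among them GON4L at -0.86 (SE 0.17) and SCAPER at -0.48 (SE 0.10), each with a limma adjusted p of 0.0892. The splicing factor SRSF11 stood at -0.51 (SE 0.11, limma adjusted p 0.101) and GALNT7 at -0.78 (SE 0.17, 0.102). There were 2713 probes with an unadjusted p under 0.05 where 1389 would be expected. The other probes of GON4L and SCAPER stood between -0.02 and -0.14, and those of SRSF11 between -0.51 and 0.04. The count of probes past the threshold was 2 without high-RFI replicate 1, 4 without high-RFI replicate 8 and 7 without restricted replicate 3, 1 without high-RFI replicate 7 or restricted replicate 6, 7 or 8, and 0 without any other pig or without the 4 arrays of slide 3.

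Proteasome genes were higher as a group after restriction, in 18 of 18 cases (mean 0.19, camera adjusted p 1.71e-06; -0.57 under the planned normexp correction), and 3 rose when adjusted over the list alone. Their call was lost with an estimated correlation (p 0.0336, adjusted p = 0.622). PSMB3 stood at 0.33 (SE 0.10), PSMD3 at 0.28 (SE 0.08) and PSMA3 at 0.17 (SE 0.07), while PSMA4 stood at 0.53 (SE 0.16) on its brightest probe and at -0.04 and -0.05 on the others. The shift was 0.17 (0.07 to 0.28) with slide as a block, 0.19 on both scan days, and positive on 6 of 6 slides, and the call held without any 1 pig. Cytosolic ribosomal proteins were higher in 38 of 39 cases (mean 0.070, camera adjusted p 0.00965; adjusted p = 0.857 with an estimated correlation), with RPL10A at 0.14 (SE 0.08), RPL5 at 0.14 (SE 0.08) and RPS15 at 0.11 (SE 0.07). This shift was at percentile 87.6 of random lists matched on signal (middle 95% from 0.019 to 0.083), so it lay within what equally bright genes showed. Genes of glycolysis were higher in 13 of 15 cases (mean 0.13, camera adjusted p 0.0444; adjusted p = 0.857 with an estimated correlation), with the hexokinase HK2 at 0.51 (SE 0.19), ENO3 at 0.15 (SE 0.10), PGAM1 at 0.26 (SE 0.16) and LDHA at 0.13 (SE 0.09). The planned normexp correction turned both means, to -0.74 and -0.66, and both calls were lost with slide as a block, at 0.06 (-0.06 to 0.18, camera adjusted p 0.0596) and 0.13 (-0.03 to 0.29, 0.0853). On scan days 1 and 2 their shifts were 0.07 on both and 0.23 and 0.03, with positive signs on 3 and 5 of 6 slides. Without high-RFI replicate 2 the ribosomal mean was 0.035 (camera adjusted p 0.37) and that of glycolysis 0.08 (0.395). The ribosomal call was also lost without restricted replicate 3 (0.0568) or 6 (0.0596). That of glycolysis was lost without high-RFI replicate 1 (0.143) or restricted replicate 1 (0.0604), 2 (0.0928), 3 (0.0568), 6 (0.229) or 7 (0.0517). Quantile normalization ended both calls, at 0.028 (0.214) and 0.09 (0.0572). The glycolysis call was also lost without the 4 arrays of slide 3 (0.0923), with robust normexp on the negative controls (0.0789) and with scan day as a block (0.0525).

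Lists of immune, vascular and proliferation genes were called lower after restriction. Of 100 splits of these pigs, the real one included, 53 called at least 7 lists, so chance is not excluded for these shifts. The major histocompatibility complex was lower in 16 of 17 cases (mean -0.18, camera adjusted p 0.00117; adjusted p = 0.807 with an estimated correlation). SLA-DMB stood at -0.26 (SE 0.14), SLA-8 at -0.25 (SE 0.12), SLA-DMA at -0.24 (SE 0.11) and B2M at -0.15 (SE 0.11). The SLA values were marked uncertain by a rule set in advance for all SLA genes. Whether SLA-DMA and SLA-DMB have near-identical copies was not checked. Leukocyte and macrophage markers were lower in 12 of 15 cases (mean -0.28, camera adjusted p 0.013; adjusted p = 0.807 with an estimated correlation), with the lysozyme LYZ at -1.12 (SE 0.52), S100A12 at -0.55 (SE 0.37), ITGB2 at -0.43 (SE 0.24) and AIF1 at -0.39 (SE 0.18). Endothelial and smooth muscle markers were lower in 9 of 12 cases (mean -0.20, camera adjusted p 0.0425; adjusted p = 0.807 with an estimated correlation), with FLT1 at -0.76 (SE 0.30), PECAM1 at -0.39 (SE 0.18), RGS5 at -0.33 (SE 0.18) and CDH5 at -0.25 (SE 0.15). Cell cycle genes were lower in 7 of 9 cases (mean -0.20, camera adjusted p 0.0439; adjusted p = 0.807 with an estimated correlation). CENPF stood at -0.73 (SE 0.23), MCM3 at -0.39 (SE 0.26), TOP2A at -0.29 (SE 0.19) and CDK1 at -0.20 (SE 0.17), and 1 fell when adjusted over the list alone. The planned normexp correction turned the leukocyte and cell cycle means, to 0.17 and 0.28.

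With slide as a block the shifts of the histocompatibility, leukocyte, endothelial and cell cycle lists were -0.25 (-0.49 to -0.01), -0.30 (-0.70 to 0.09), -0.16 (-0.37 to 0.05) and -0.20 (-0.42 to 0.01). On scan day 1 they were -0.23, -0.30, -0.19 and -0.32, on scan day 2 they were -0.13, -0.26, -0.20 and -0.09, and they were negative on 4, 4, 5 and 6 of 6 slides. All 4 calls were lost without restricted replicate 3 (camera adjusted p 0.0568, 0.0568, 0.0618 and 0.0568), where the histocompatibility mean was -0.11, as it was without restricted replicate 1. The last 3 calls were also lost without restricted replicate 1 (each 0.0604) or 2 (each 0.0711). Without high-RFI replicate 2 the endothelial mean was -0.13 (0.129) and the cell cycle mean -0.14 (0.111). The endothelial call was lost too without restricted replicate 5 (0.0775), and the cell cycle call without high-RFI replicate 1 (0.112) or 7 (0.0599) or restricted replicate 6 (0.0836) or 7 (0.0517). Planned normexp (-0.41, 0.0959), the deposited values (0.0641) and the mean of a gene's probes (-0.12, 0.0894) also ended the endothelial call. The cell cycle call was lost with quantile normalization (0.113), no filter on dim probes (-0.135, 0.05), the mean of a gene's probes (0.0667), slide 3 left out (0.0768) and scan day as a block (0.0525). The 5 measured genes of the circadian clock were all higher after restriction (mean 0.48), a list just short of the threshold (camera adjusted p 0.0529; exact two-sided permutation p 0.0255, adjusted 0.272). In all, 7 of 32 lists were called, with 3 without high-RFI replicate 2, 12 without high-RFI replicate 3, and 3, 1 and 4 without restricted replicates 2, 3 and 6. The number was 0 with an estimated correlation, with fry or with the adjusted exact permutation, and 4 with the unadjusted one. Among 100 random splits of these pigs 53 called at least 7 lists and 10 gave at least 1 probe, so chance is not excluded for either count.

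The third comparison set the lines side by side at the same feeding level. CD40 again fell in low-RFI pigs, to 0.48 ± 0.40 (n = 7) against 1.73 ± 0.37 (n = 8), a difference of -1.25 (SE 0.17, limma adjusted p 0.00126). RSF1, a chromatin remodelling factor, rose from 3.15 ± 0.26 to 3.94 ± 0.21, a difference of 0.80 (SE 0.11, limma adjusted p 0.00191), and C4H8orf37 rose by 0.86 (SE 0.15, limma adjusted p 0.0123). The ubiquitin hydrolase UCHL1, best known from neurons, fell by 1.07 (SE 0.21, limma adjusted p 0.0389), and the secreted glutathione peroxidase GPX3 fell by 0.99 (SE 0.20, limma adjusted p 0.0397). OAZ3 fell by 0.68 (SE 0.13, limma adjusted p 0.0256), and its probe of lower mean was at least 8.07-fold lower (limma adjusted p 0.000279). The reason for this disagreement was again not tested. COQ5, a methyltransferase of coenzyme Q synthesis, fell by 0.52 (SE 0.11, limma adjusted p 0.0476).

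At the same feeding level 45 probes passed the threshold, 20 higher and 25 lower in low-RFI pigs, and 2830 had an unadjusted p under 0.05 where 1389 would be expected. These probes included 5 of RPL6, a protein of the large ribosomal subunit, from 0.42 to 0.62, 2 of DLD at -0.75 and -0.49, and 1 of the transcription factor KLF3 at 1.37, all chosen after their values were seen. The brightest RPL6 probe, at 0.18, did not pass (adjusted p 0.429). With slide as a block CD40 at -1.18 (limma adjusted p 0.00173), RSF1 at 0.79 (0.0237) and C4H8orf37 at 0.85 (0.04) were still past the threshold, and OAZ3 (0.0693), UCHL1 (0.0778), COQ5 (0.0778) and GPX3 (0.082) were not, at -0.67, -1.07, -0.51 and -0.91. All 7 genes kept their sign on 6 of 6 slides. On scan days 1 and 2 the differences were -1.02 and -1.54 for CD40, 0.99 and 0.59 for RSF1, 0.74 and 1.03 for C4H8orf37, -0.70 and -1.52 for UCHL1, -1.06 and -0.93 for GPX3, -0.55 and -0.81 for OAZ3, and -0.46 and -0.60 for COQ5. The count was 18 without low-RFI replicate 1, 20 without low-RFI replicate 2 or 5, 22 without 6, 26 without high-RFI replicate 7, 26, 26, 23 and 20 without restricted replicate 2, 4, 6 and 8, and 68 without restricted replicate 1. Median centring ended the calls of UCHL1 (adjusted p 0.0697), GPX3 (0.0707) and COQ5 (0.199), and quantile normalization those of UCHL1 (0.0514) and GPX3 (0.0559). With no filter on dim probes UCHL1 (0.099), GPX3 (0.102), OAZ3 (0.0662) and COQ5 (0.126) missed the threshold, and COQ5 did with the deposited values (0.0591). The replicate number as a block ended the calls of C4H8orf37 (0.82, 0.0544), UCHL1 (0.0825), GPX3 (0.109), OAZ3 (0.0634) and COQ5 (0.0825). Without the 4 arrays of slide 3, 15 probes passed, and UCHL1 (0.0654), GPX3 (0.0804) and COQ5 (0.171) did not. A block for scan day ended the calls of GPX3 (0.0516) and COQ5 (0.0523), and robust normexp on the negative controls those of OAZ3 (-0.36, 0.189) and COQ5 (-0.50, 0.0562). The planned normexp correction ended all 7 calls, with CD40 at -0.74, RSF1 at 1.32, C4H8orf37 at 0.27, UCHL1 at -0.39, GPX3 at -0.50, OAZ3 at -0.59 and COQ5 at -0.10. In the 23 fits that left out 1 pig COQ5 missed the threshold in 20, GPX3 in 12, UCHL1 in 11 and OAZ3 in 5, and the other 3 genes in 0.

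Ribosomal, fast fibre and cell cycle genes were higher as groups in low-RFI than in restricted high-RFI pigs. Cytosolic ribosomal proteins were higher in 38 of 39 cases (mean 0.14, camera adjusted p 8.86e-12; adjusted p = 0.54 with an estimated correlation; exact two-sided permutation p 0.0121, adjusted 0.169), with RPL14 at 0.36 (SE 0.13), RPL23 at 0.23 (SE 0.08), RPLP0 at 0.23 (SE 0.08) and RPS12 at 0.18 (SE 0.07). None of them passed when adjusted over the list alone. Fast fibre genes were higher in 15 of 16 cases (mean 0.13, camera adjusted p 0.0168; adjusted p = 0.54 with an estimated correlation), with the calcium buffer PVALB at 0.55 (SE 0.28) and MYL1 at 0.16 (SE 0.10). MYH1 stood at 0.22 (SE 0.12) and MYH2 at 0.25 (SE 0.13), both uncertain as near-identical copies, and the other probes of MYH2 stood at -0.13 and -0.16. Cell cycle genes were higher in 8 of 9 cases (mean 0.23, camera adjusted p 0.0193; adjusted p = 0.54 with an estimated correlation; -0.13 under the planned normexp correction). BIRC5 stood at 0.57 (SE 0.13), CENPF at 0.61 (SE 0.24), TOP2A at 0.26 (SE 0.19) and CCNB1 at 0.20 (SE 0.13), and 1 rose when adjusted over the list alone. The 3 slide-blocked shifts were 0.14 (0.02 to 0.26), 0.12 (0.001 to 0.24) and 0.22 (-0.001 to 0.44). On scan days 1 and 2 they were 0.19 and 0.08, 0.11 and 0.15, and 0.32 and 0.13, with positive signs on 6, 5 and 5 of 6 slides. The fast fibre call was lost without restricted replicate 4 (camera adjusted p 0.0822), and the cell cycle call without low-RFI replicate 1 (0.117) or restricted replicate 2 (0.0569). Quantile normalization ended both calls, at 0.07 (0.543) for fast fibre and 0.19 (0.0628) for cell cycle genes, and robust normexp on the negative controls ended the former (0.09, 0.0808).

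Genes of 5 mitochondrial lists were lower as groups in low-RFI than in restricted pigs, and ATP synthase (mean -0.08, camera adjusted p 0.0557) was not called. All 5 lists turned sign under the planned normexp correction, to means between 0.29 and 0.47. Its poor fits, which compressed bright genes, included restricted replicates 2, 3 and 5 and low-RFI replicate 4. Robust normexp on the negative controls turned 0 called lists. The tricarboxylic acid cycle with pyruvate dehydrogenase was lower in 13 of 13 cases (mean -0.17, camera adjusted p 0.000804; adjusted p = 0.54 with an estimated correlation), with DLD at -0.38 (SE 0.09), PC at -0.24 (SE 0.13), MDH2 at -0.22 (SE 0.12) and IDH3B at -0.20 (SE 0.11). Respiratory complexes II to IV were lower in 12 of 12 cases (mean -0.15, camera adjusted p 0.00145; adjusted p = 0.54 with an estimated correlation), with CYCS at -0.31 (SE 0.12), SDHA at -0.30 (SE 0.13), COX6A1 at -0.26 (SE 0.13) and COX6C at -0.17 (SE 0.08). Complex I was lower in 9 of 10 cases (mean -0.14, camera adjusted p 0.0168; adjusted p = 0.54 with an estimated correlation), with NDUFB9 at -0.41 (SE 0.14), NDUFS6 at -0.15 (SE 0.09) and NDUFA4 at -0.15 (SE 0.10). Genes of fatty acid uptake and oxidation were lower in 14 of 19 cases (mean -0.14, camera adjusted p 0.0168; adjusted p = 0.54 with an estimated correlation), with DECR1 at -0.48 (SE 0.14), HADH at -0.28 (SE 0.10), ACADS at -0.26 (SE 0.13) and ETFA at -0.20 (SE 0.10). Mitochondrial ribosomal proteins were lower in 10 of 13 cases (mean -0.09, camera adjusted p 0.0379; adjusted p = 0.54 with an estimated correlation), with MRPL24 at -0.37 (SE 0.15), MRPL13 at -0.22 (SE 0.13), MRPS18B at -0.19 (SE 0.09) and MRPL18 at -0.13 (SE 0.09). Adjusted over the list alone, 1 gene each of the tricarboxylic acid and fatty acid lists fell. With slide as a block the 5 shifts were -0.18 (-0.35 to -0.01), -0.15 (-0.32 to 0.03), -0.13 (-0.29 to 0.02), -0.14 (-0.37 to 0.08) and -0.10 (-0.23 to 0.03), and the call of the last was lost (camera adjusted p 0.0554). On scan day 1 they were -0.20, -0.20, -0.15, -0.18 and -0.08, on scan day 2 they were -0.14, -0.10, -0.13, -0.12 and -0.12, and they were negative on 6, 5, 6, 4 and 4 of 6 slides. Without restricted replicate 2 or 4 the calls of complex I (camera adjusted p 0.0569 and 0.0582), fatty acid oxidation (0.0658 and 0.0582) and mitochondrial ribosomal proteins (0.0569 and 0.0582) were lost. That of mitochondrial ribosomal proteins was also lost without low-RFI replicate 2 (0.0836), 3 (0.0625) or 6 (0.0647) or restricted replicate 1 (0.0975), 3 (0.0692) or 5 (0.114). Quantile normalization ended the calls of fatty acid oxidation (0.0628) and of mitochondrial ribosomal proteins (-0.06, 0.222).

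Stress and fasting-responsive genes were also lower as groups in low-RFI than in restricted pigs. Heat shock and chaperone genes were lower in 14 of 14 cases (mean -0.33, camera adjusted p 5.31e-05; adjusted p = 0.54 with an estimated correlation; 0.16 under the planned normexp correction). HSPH1 stood at -1.32 (SE 0.44), BAG3 at -0.75 (SE 0.28), HSPA1L at -0.28 (SE 0.15) and HSPD1 at -0.23 (SE 0.10). Fasting-responsive targets of FOXO and PPAR factors were lower in 13 of 19 cases (mean -0.30, camera adjusted p 0.0193; adjusted p = 0.54 with an estimated correlation), and 2 fell when adjusted over the list alone. The glucocorticoid-induced FKBP5 stood at -1.47 (SE 0.42), PPARGC1A, a coactivator of mitochondrial biogenesis, at -1.32 (SE 0.38), CEBPD at -0.67 (SE 0.33) and FOXO1 at -0.43 (SE 0.18). Immediate early genes were lower in 12 of 15 cases (mean -0.32, camera adjusted p 0.0379; adjusted p = 0.748 with an estimated correlation), with NR4A3 at -1.59 (SE 0.95), GADD45G at -0.84 (SE 0.34), KLF2 at -0.59 (SE 0.27) and KLF4 at -0.55 (SE 0.36). Proteasome genes were lower in 15 of 18 cases (mean -0.08, camera adjusted p 0.0323; adjusted p = 0.724 with an estimated correlation; 0.48 under the planned normexp correction). PSMB3 stood at -0.26 (SE 0.10), PSME3 at -0.17 (SE 0.09) and PSMB4 at -0.14 (SE 0.08). PSMA4 stood at -0.40 (SE 0.17) on its brightest probe and at 0.03 and 0.06 on the others. No gene of the heat shock, immediate early or proteasome list passed, also when adjusted over the list alone.

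With slide as a block the shifts of the heat shock, fasting, immediate early and proteasome lists were -0.31 (-0.62 to -0.003), -0.31 (-0.72 to 0.09), -0.28 (-1.09 to 0.53) and -0.07 (-0.18 to 0.04), and the last 2 calls were lost (camera adjusted p 0.119 and 0.0684). On scan day 1 they were -0.38, -0.30, -0.75 and -0.04, and on scan day 2 they were -0.23, -0.32, 0.26 and -0.13. The mean shift of the immediate early list was thus not negative on day 2, and whether the days differed was not tested. They were negative on 5, 5, 3 and 4 of 6 slides. The fasting call was lost without restricted replicate 7 (camera adjusted p 0.119) or 8 (0.0923, mean -0.20). The immediate early call was lost without low-RFI replicate 1 (0.201, mean -0.15), 5 (0.12) or 7 (0.136, mean -0.21) or restricted replicate 2 (0.0569), 3 (0.0804), 7 (0.205) or 8 (0.232, mean -0.20), and without low-RFI replicate 6 its mean was -0.53. It was also lost with quantile normalization (0.0643), planned normexp (-0.046, 0.343), the replicate number as a block (-0.23, 0.0907), slide 3 left out (-0.07, 0.574) and scan day as a block (0.0519). Leaving out slide 3 ended the fasting call (-0.21, 0.112) as well, and quantile normalization the proteasome call (-0.05, 0.227). The proteasome call was lost without low-RFI replicate 1 (0.129), 2 (0.0933) or 6 (0.0587) or restricted replicate 2 (0.0569), 4 (0.134) or 5 (0.0706). Of 32 lists, 12 were called, and 6 without restricted replicate 2. The number was 0 with an estimated correlation, with fry or with the adjusted exact permutation, and 7 with the unadjusted one. UCHL1 was the 1 gene of 5 nerve and Schwann cell markers that fell (list mean -0.20, camera adjusted p 0.166), and GPX3 the 1 of 26 antioxidant and detoxification genes (list mean -0.03, camera adjusted p 0.504). In the lists that were not called, mean and median could differ in sign. This was so for fatty acid uptake and oxidation between the lines at free feeding (0.01 and -0.09) and satellite cell genes at the same feeding level (-0.06 and 0.003).

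**Figure D3:**
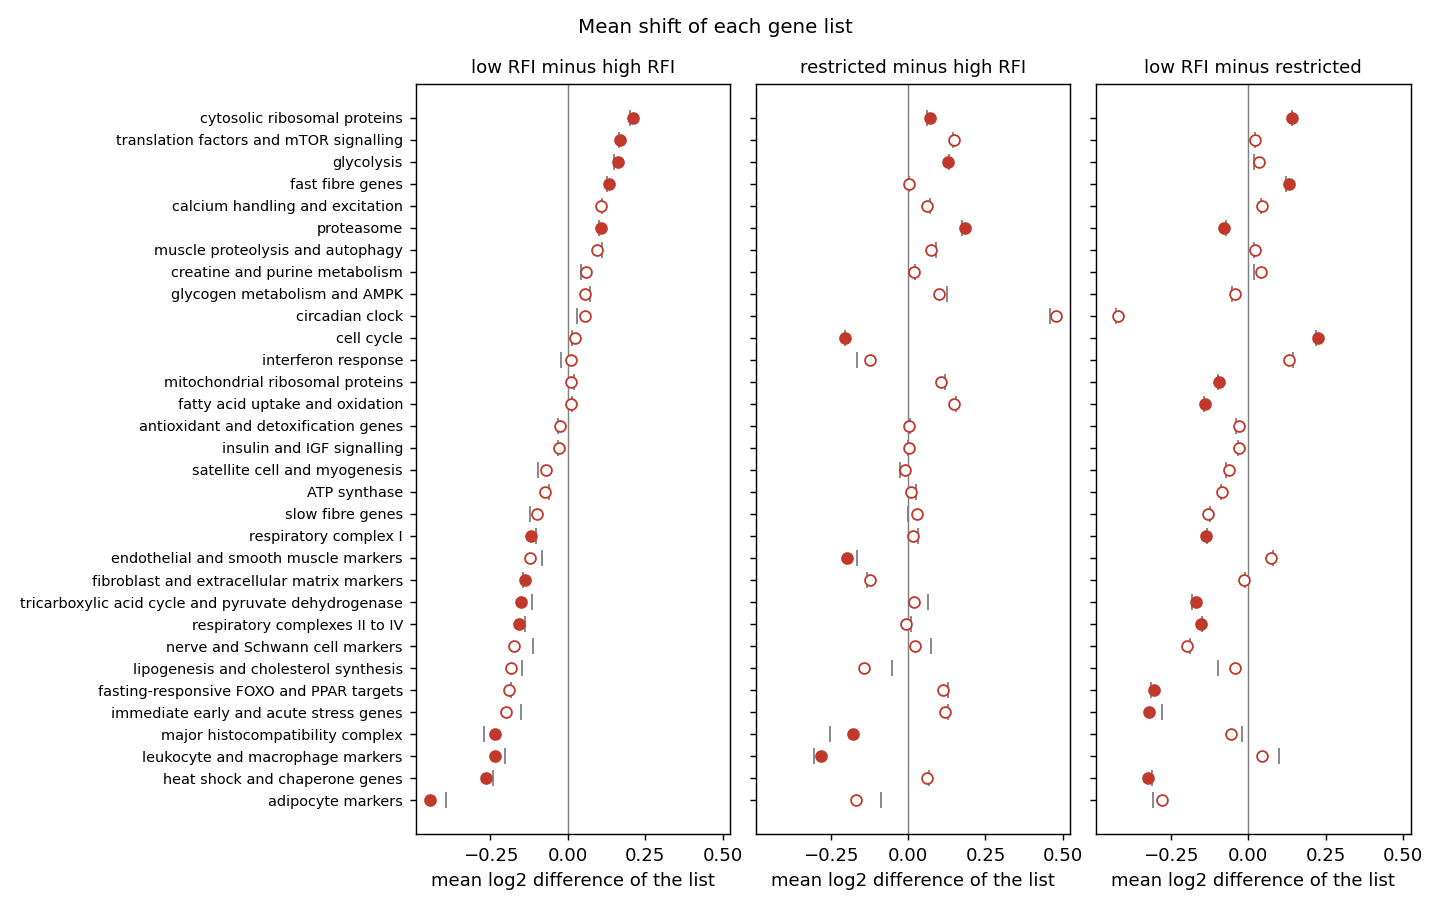
Mean log2 difference (horizontal axis) of the measured genes of 32 gene lists (vertical axis) in the 3 comparisons. Filled points mark lists with a camera adjusted p under 0.05 at a preset correlation of 0.01, open points the others, and grey ticks the mean difference with slide as a block. The ribosomal list stands at 0.21, 0.070 and 0.14.

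The comparisons were then set against each other across probes, which are not independent replicates. The low and high lines differed in the same direction at both feeding levels for 13 probes past the threshold in both comparisons, of 13 such probes, and 3 of their genes had a symbol. Of these probes 1 was higher and 12 were lower in low-RFI pigs. Both comparisons used the same low-RFI arrays, which favours shared probes of 1 sign, and what unchanged groups would share was not tested. Differences of the line at the same feeding level and at free feeding correlated across 27326 probes (Pearson r 0.62, Spearman rho 0.53). Unchanged groups were drawn by removing the group means and shuffling all arrays among the groups. The shuffling was not kept within slide, whereas the real groups were spread over all slides. These unchanged groups gave a mean r of 0.54 (SD 0.12), and 25 of 100 draws reached the observed r. With the low-RFI pigs split between the comparisons the observed r was 0.24. The covariance was 0.0397 against 0.0247 (SD 0.00884) for unchanged groups. Differences after feed restriction and between the lines at free feeding, which share the high-RFI arrays, correlated at r 0.42 (rho 0.43) against 0.46 (SD 0.14) for unchanged groups, and at 0.037 with the high-RFI pigs split. Their covariance was 0.0232 against 0.0203 (SD 0.00868), so these draws showed no shared direction of the line and of feed restriction. They cannot exclude 1, since slide differences enter the draws in another way than the real groups.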

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

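Among 456 sets of values, each 1 gene or list in 1 group, 30 held a pig whose gap to the nearest other pig was a large share of the group's range by Dixon's criterion. Chance gives about 1 in 20, or 22.8 sets. There were 15 sets in high-RFI, 8 in low-RFI and 7 in restricted pigs, and whether the groups differ in this was not tested.

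High-RFI replicate 2 stood apart for SAL1 (-0.219, others -2.653 to -1.709), PGAM1 (4.38), PGAM2 (8.169), FN1 (4.252), COL4A1 (3.167), RPS15 (7.523), RGS5 (2.74), CDH5 (2.287), CENPF (-1.743), PC (2.135) and the ribosomal list (7.439, others 7.645 to 7.824). In the same group, replicate 1 stood apart for MTHFD1 (3.538), replicate 3 for PPARGC1A (3.35), and replicate 7 for PSMD3 (6.198) and PSMA3 (5.608). Low-RFI replicate 7 stood apart for CD40 (1.318, others 0.066 to 0.579), SDHD (6.342) and ETFA (4.813), replicate 5 for CEBPA (2.563), the adipocyte list (1.135, others -0.068 to 0.387) and the antioxidant list (3.241), and replicate 4 for MAPK12 (4.026) and the creatine and purine list (4.456). Restricted replicate 8 stood apart for PSMC5 (6.529), FBN1 (-1.018), RSF1 (2.572) and the antioxidant list (3.328), replicate 5 for RPL14 (7.397), replicate 7 for FLT1 (0.78) and replicate 3 for BIRC5 (1.13).

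The test of a sequence variant under 1 CD40 probe and the ribosomal check without 1 pig were chosen after the result was seen, and the exact permutation tests after the data were seen but before their own values. For the numbers of calls, random splits of the pigs, not kept within slide, were counted with the real one included. For probes, 1 of 100 splits gave as many as the real 34 between the lines at free feeding (highest other 3), and 1 of 100 splits as many as the real 45 at the same feeding level (highest other 1). In addition, 1 of 100 splits gave as many as the real 38 in the F test (highest other 3), so chance can be excluded for these 3 counts at 5 in 100. After restriction 10 of 100 splits gave as many as the real 1 (highest other 2), so chance cannot be excluded. For lists, 10 of 100 splits gave as many as the real 13 at free feeding (highest other 18), and 53 of 100 splits as many as the real 7 after restriction (highest other 17). At the same feeding level 2 of 100 splits gave as many as the real 12 (highest other 16). Only this last count was rarer than 5 in 100, without adjustment for the 3 list counts. With an estimated correlation, fry or adjusted exact permutation 0 of 32 lists were called there, so chance is not excluded for its list calls.

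The higher ribosomal list of low-RFI pigs was weighed against 3 explanations. Its shift of 0.21 was at percentile 100 of 10000 random lists matched on signal, whose median was 0.062 and whose middle 95% ran from 0.012 to 0.11. Equally bright genes were thus also higher. This speaks against intensity-dependent normalization as the whole cause, but not as a part of it. The random lists also leave out the correlation among ribosomal genes. The planned normexp fit, poor on 5 arrays, turned the shift to -0.02, while robust normexp on the negative controls turned 0 called lists. The lower end of the interval with slide as a block was 0.08, which speaks against slide differences. Low-RFI pigs were also above restricted pigs (exact permutation p 0.0121), while restricted pigs were not above high-RFI pigs by that test (exact p 0.228), so lower feed intake may not be the whole cause. Without high-RFI replicate 2, a check added after the data were seen, the shift was 0.18 (exact permutation p 0.00233), and a difference between the lines remains a possible reading.

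The lower CD40 of low-RFI pigs was weighed against 3 explanations. All 3 of its probes were lower at an unadjusted p under 0.05, which speaks against a sequence variant under only 1 of them. That all 3 had passed the threshold was known when this test was chosen, so its outcome was fixed. Whether the probes target separate sequence was not checked, so a variant under overlapping probes stays open. The 10 nearest measured genes were at percentile 83.7 of such windows, under the preset limit of 90, but this test took only the brightest probe with a symbol of each gene. That probe of the neighbour PCIF1 stood at 0.68 (limma p 0.000395, adjusted p 0.118). A probe without a symbol, described as PCIF1's protein, was higher at 0.996 (limma adjusted p 0.00183), and 1 described as sorting nexin-21, of the same stretch, was lower at -0.86 (0.0129). Both were chosen after their values were seen, so a wider chromosome segment stays open. The upper end of the interval with slide as a block was -1.047, which speaks against slide differences. A difference between the lines near or in the gene itself, or in the cells that express it, was not tested.

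The lower adipocyte list of low-RFI pigs was weighed against 3 explanations, and none was settled. An exact permutation of the list's mean per pig gave p 0.179, so fewer fat cells in the low-RFI samples were neither shown nor excluded. Of the markers 10 of 11 were lower, with CIDEC at -1.14 and FABP4, the marker with the highest array signal, at -0.53. The adipocyte mean less the endothelial and smooth muscle mean gave an exact permutation p of 0.245, so a lower share of all cells other than muscle fibres stays open. With slide as a block the shift was -0.39 (upper end 0.279) against -0.45 without (upper end 0.149), so the block took little of it, but both intervals include 0 and slide differences were not excluded. Without high-RFI replicate 2 the shift was -0.27 (camera adjusted p 0.0539), and without replicate 1 it was -0.33 (0.0865).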

How the results depend on the processing

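Most other settings were chosen before the data were examined. Fits without slide 3, with scan day as a block, with exact permutation of list means, with 3 further normexp estimates and, for lists, without each pig in turn were chosen after. A case is 1 result under 1 setting. Among the named results, 3 at free feeding, 0 after restriction and 7 at the same feeding level were past the threshold. Only these could lose a call, so cases kept by the other named results do not show that calls are stable. Over 9 settings chosen before, namely median centring, quantile normalization, planned normexp, the deposited values, both filters, trend and robust variance, slide as a fixed block and the replicate block, 140 named results kept direction and side of the threshold in 1153 of 1241 cases. In 36 cases the call was lost, in 5 it was gained and in 47 the sign turned, all 47 under planned normexp. Leaving out each pig, also chosen before, is not in these counts, and in its 23 fits the calls of COQ5, GPX3, UCHL1 and SAL1 were lost in 20, 12, 11 and 2, and that of OAZ3 in 14 at free feeding and 5 at the same feeding level. Array weights, slide as a random block and fits of 2 groups were run for the counts of probes only. For the 32 called lists there were 11 settings, the same except the filter to all arrays, with an estimated correlation, fry and the mean of a gene's probes added. They kept both in 243 of 352 cases, lost the call in 92, of which 32 came from the estimated correlation and 31 from fry, and turned in 17. Without slide 3, with scan day as a block and with robust normexp on the negative controls, the named results kept both in 410 of 420 cases and lost the call in 10. With these settings and exact permutation the called lists kept both in 83 of 128 cases, with none turned. Where no cause is given, the cause was not tested. Low signal limits the results, since on slide 3 between 41.7% and 58.8% of probes were well above background.

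Counts of probes past the threshold were 34 between the lines at free feeding, 1 after restriction, 45 at the same feeding level and 38 in the F test. In that order, they were 14, 0, 10 and 15 at an adjusted p of 0.01, 22, 0, 18 and 22 with no filter on dim probes, 52, 0, 76 and 92 with trend and robust variance, and 0, 0, 0 and 0 with planned normexp. Slide 3 left out gave 18, 0, 15 and 20, with fewer arrays, and normexp on the negative controls gave 0, 0, 9 and 0. The first 3 counts were 19, 0 and 25 with slide as a fixed block, 20, 1 and 21 with the deposited values and 3, 0 and 11 with the mean of a gene's probes, where fewer tests were made. Array weights gave 107 at free feeding, 98 at the same feeding level and 175 in the F test. The 2 counts after restriction and at the same feeding level were 0 and 23 with median centring, 0 and 25 with only the 2 groups compared, 0 and 22 with normexp without 5 arrays, and 2 and 98 with slide as a random block, where the F test gave 138. After restriction quantile normalization gave 0, robust normexp on the negative controls 0 and scan day as a block 3. Only probes well above background on all arrays gave 18 at free feeding and 66 in the F test. The replicate number as a block gave 0 and 20, and 19 in the F test. In the order of the comparisons 2 of 7, 4 of 8 and 1 of 7 pairs correlated over 0.1, and 0, 4 and 1 pigs matched their own number best. The numbers were taken as names, but a pairing of restricted with high-RFI pigs, where 4 of 8 matched, was not excluded. Leaving out 1 pig gave 22 to 40, 0 to 7, 18 to 68 and 24 to 70.

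Lists called numbered 13, 7 and 12. They were 0, 0 and 0 with an estimated correlation, 1, 0 and 0 with fry and 1, 0 and 0 with exact permutation. Leaving out 1 pig gave 11 to 14, 1 to 12 and 6 to 13. After restriction they were 16 with planned normexp, 11 with the deposited values and 11 with no filter, and at the same feeding level 7 with quantile normalization. The correlation of restriction with line at free feeding was 0.741 with planned normexp, 0.037 with the shared group split between the comparisons and 0.596 over probes past the threshold in either comparison. That of line at the same feeding level with line at free feeding was -0.437, 0.237 and 0.924.

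Planned normexp fitted background SDs of 196.2 to 6065.1 on low-RFI replicate 4, high-RFI replicate 1 and restricted replicates 2, 3 and 5. The 90th percentiles of these 5 arrays were 0.27 to 1.96 against 2.53 to 2.69 on the others. This compressed bright genes on those arrays, and its robust form on the negative controls turned 0 of 140 named results but ended 4 calls, with OAZ3 at -0.31 (adjusted p 0.254) at free feeding and -0.36 (0.189) at the same feeding level, SAL1 at -0.92 (0.0838) and COQ5 at -0.50 (0.0562). The negative control fit without that form turned 33 and had 1 control spot at 149857.5 on restricted replicate 1, and planned normexp without the 5 arrays turned 9. Under planned normexp these values turned at free feeding: TPM1 -0.091, TNNI2 -0.015, TNNC2 -0.111, RPS12 -0.001, PSMC5 -0.062, PSMB5 -0.035 and AQP7 0.02, and the lists of glycolysis -0.055, fast fibre -0.136, ribosomal -0.023 and proteasome -0.091. After restriction they were PGAM1 -0.603, ENO3 -0.675, LDHA -0.681, RPL10A -0.723, RPL5 -0.686, RPS15 -0.731, PSMD3 -0.558, PSMA4 -0.32, PSMA3 -0.692, ITGB2 0.095, S100A12 0.515, CENPF 0.429, TOP2A 0.538, MCM3 0.624, CDK1 0.438 and GALNT7 0.117, and the lists of glycolysis -0.656, ribosomal -0.742, proteasome -0.572, leukocyte 0.167 and cell cycle 0.283. At the same feeding level they were NDUFB9 0.185, NDUFS6 0.437, NDUFA4 0.426, CYCS 0.293, SDHA 0.338, COX6C 0.422, COX6A1 0.395, DLD 0.268, IDH3B 0.434, MDH2 0.404, PC 0.151, HADH 0.341, ACADS 0.392, ETFA 0.446, MRPL24 0.275, MRPL18 0.5, PSMA4 0.257, PSME3 0.13, PSMB4 0.459, FOXO1 0.088, HSPD1 0.412, CENPF -0.234, CCNB1 -0.177 and TOP2A -0.384. Its turned lists were complex I 0.396, complexes II to IV 0.474, tricarboxylic acid cycle 0.426, fatty acid 0.288, mitochondrial ribosomal 0.365, proteasome 0.481, heat shock 0.159 and cell cycle -0.13.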

Other observations

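Of the erythroid markers only CA1, a carbonic anhydrase of red blood cells, was measured, and its list was not tested. CA1 stood at 0.43 (SE 0.20, limma p 0.0376, adjusted p 0.415) in low-RFI against high-RFI pigs, at 0.35 in restricted against high-RFI pigs and at 0.08 in low-RFI against restricted pigs, and passed in none. It was well above background on 6 of 7 low-RFI, 5 of 8 high-RFI and 6 of 8 restricted arrays.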
